A study of Phaseolus vulgaris with 36 samples.

How the data were processed

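Total RNA was isolated from pods of untreated plants with a TRIzol-type reagent and sequenced as 75-base single reads of TruSeq libraries, per the labels' protocols. The series has 36 samples in 12 groups of 3, taken from the labels: 4 accessions at 3 stages. The replicate numbers are those of the labels.

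The deposited files hold 1 table per sample with a transcript's length, effective length, estimated count and TPM, a transcript abundance scaled for length and library size. These are the columns of a kallisto table, and kallisto, limma and edgeR are named without versions in the submitters' processing notes. The estimated counts were deposited by the authors without normalization and need not be whole numbers. The TPM values were deposited by the authors and are scaled to the same total in each sample. The genome build, the annotation, the index and the trimming of reads are not given in the sources used here. Whether strand was used is not given either, so reads of a gene and its antisense partner cannot be separated, and estimated counts of near-identical genes share reads and are uncertain. Each file has 36996 lines with its header and 36995 transcripts.

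Estimated counts were summed over the transcripts of a gene, taken from the identifier, giving 27433 genes, and rounded to whole numbers. TPM values entered no test. The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr (minimum count 10, minimum total count 15) and a quasi-likelihood fit with robust estimation over all 36 samples and 12 groups. The filter kept 20966 genes and removed 6467. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested and a log2 fold change of at least 1 in size, a 2-fold change. CPM values in the text use TMM-scaled library sizes, and log2 CPM used a prior count of 2. Standard errors were derived from the F statistic of each contrast. The difference of a step between accessions was tested with a quasi-likelihood F-test over the 4 accessions, adjusted over all genes tested.

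The stage comparisons follow the series design. R9 was not tested against R7. Accession comparisons were MIDAS minus G12873 and SXB405 minus ICA Bunsi at each stage. Candidate genes were tested as MIDAS minus the mean of the other 3 accessions. Accession, dehiscence and domestication cannot be told apart for G12873 and MIDAS, each the only one of its kind.

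Gene names were to come from a reference table of 34165 genes of the assembly P. vulgaris v2.0, but 0 of the 27433 identifiers matched it and it gave no descriptions. The 27 gene lists fixed before the data were examined, and the tests planned on them, were therefore not run. Named genes follow the rule fixed for that case: at most 2 identifiers up and 2 down per comparison, with a mean of at least 1 CPM in every group compared, ranked by the mean log2 fold change among genes called in every part of the comparison, plus 3 candidates. From R8 to R9 no gene was called in all 4 accessions, so the rule was applied within each accession that had called genes.

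Total counts ranged from 2032506 to 15202576. The precision was set by the counts outside the co-varying set of 10 genes, which were found among the 50 most abundant genes by a Spearman correlation over 0.9 with the first of them. These other counts ranged from 275179 to 14904905. No 2 replicates agreed within sampling noise. Replicate numbers were checked for pairing, and none was found, though the check cannot exclude it.

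The fit was tested on simulated data. In the simulated step from R8 to R9 of G12873, run on 20685 genes, 18% of the genes changed by 2-fold and 76% of those changed by 4-fold were called, with 7 false calls. In that of MIDAS the shares were 17% and 77%, with 6 false calls. The simulation gave a gene the same spread in all groups and changed only genes over 1 CPM at R8. The real groups differ in spread, so these shares need not hold for the real steps. The closing-section statistics were tested on simulated data as well.

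Alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE size factors, the 50 most abundant genes left out, no low-count filter, no minimum fold change, transcripts in place of genes, effective lengths as an offset, a fit on the 6 samples compared, a replicate block, and leaving out each library in turn. A fit without the 8 libraries in which the co-varying set took over 50% was added after seeing the data. It leaves 1 library each in G12873 R7 and ICA Bunsi R9, assumed to vary like the other groups. Python 3.11.15 with pandas 2.3.3 read the tables and matplotlib 3.10.9 drew the plots.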

Results

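Pod transcriptomes of common bean (Phaseolus vulgaris) were measured in 4 accessions at 3 stages, from the first pod (R7) through pod filling (R8) to the mature pod (R9). The labels describe G12873 as a wild accession with fully dehiscent pods, which split open at maturity. ICA Bunsi and SXB405 are domesticated and labelled as intermediate in dehiscence, and MIDAS is domesticated and labelled indehiscent. Each of the 12 groups had 3 libraries of untreated plants, 36 in all. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so the tests measure the spread between these libraries, which may be technical. Estimated counts covered 36995 transcripts of 27433 genes, and 20966 genes had enough counts to be tested.

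Total counts ranged from 2032506 in G12873 R7 replicate 1 to 15202576 in SXB405 R7 replicate 1. A set of 10 abundant genes, led by Phvul.L001990 and Phvul.003G000408, rose and fell together over the libraries and took from 1.96% of the counts in SXB405 R7 replicate 1 to 86.5% in G12873 R7 replicate 1. In 8 libraries the set took over 50%: G12873 R7 replicates 1 and 2, ICA Bunsi R7 replicate 3 and R9 replicates 1 and 3, SXB405 R9 replicate 1, MIDAS R8 replicate 2 and MIDAS R9 replicate 1. The counts left for all other genes were 275179 and 687090 in replicates 1 and 2 of G12873 at R7, against 9976502 in replicate 3. The correlation of log2 CPM (counts scaled by library size) across genes between replicates was lowest in that group (Pearson's r from 0.707 to 0.773) and lay between 0.877 and 0.988 in the other groups.

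The first principal component, with 42.4% of the variance of the 2000 genes used, ordered the stages within each accession. The R8 libraries of the accessions stood at different places on it. Those of MIDAS lay between -60.4 and -46.9, next to the R7 libraries of MIDAS (-86.6 to -72.3). Those of G12873 lay between 51 and 60.9, next to its R9 libraries (61.7 to 80.9). The R8 libraries of ICA Bunsi spread from -33.2 to 24.9, and those of SXB405 lay between 27.5 and 43.1.

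**Figure D1:**
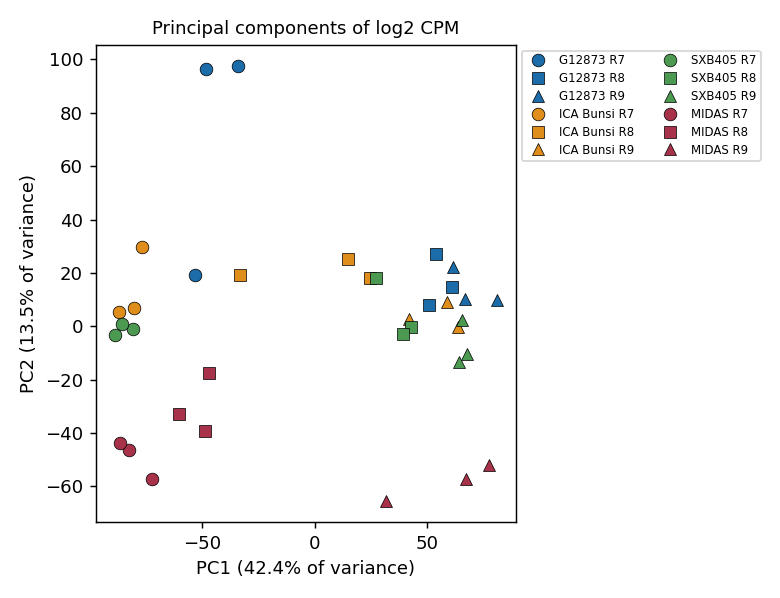
Principal components 1 and 2 of log2 CPM, with 42.4% and 13.5% of the variance; each point is 1 library, colours give the accession and symbols the stage. The R8 libraries of MIDAS lie at -60.4 to -46.9 on component 1 and those of G12873 at 51 to 60.9, while replicates 1 and 2 of G12873 at R7 stand apart on component 2.

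Between R7 and R8, the series asks which genes change as the pod fills. Large numbers of genes changed at this step in each accession. In G12873, 2488 genes rose and 2682 fell. ICA Bunsi had 2499 genes that rose and 2361 that fell, SXB405 had 2224 and 3049, and MIDAS had 1573 and 1949. In the same direction in all 4 accessions, 141 genes rose and 358 fell. G12873 and SXB405 shared 1164 rising genes, where independent lists of those sizes would share 263.9, and 43 genes that rose in G12873 fell in SXB405. They shared 1430 falling genes against 390 for independent lists, and 38 genes that fell in G12873 rose in SXB405. G12873 and MIDAS shared 242 rising genes against 186.7 for independent lists, and 190 genes that rose in G12873 fell in MIDAS. They shared 484 falling genes against 249.3 for independent lists, and 184 genes that fell in G12873 rose in MIDAS. No number for independent lists was computed for genes of opposite direction, so those counts are not read as above chance. Genes were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change. On only the 6 samples compared, G12873 had 926 rising and 996 falling genes, and 92 rose and 118 fell in all 4 accessions. The count in MIDAS was 2027 without MIDAS R7 replicate 3, and the count shared by all 4 accessions was 263 without G12873 R7 replicate 3 and 305 without MIDAS R8 replicate 1.

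Which direction held more genes turned with the settings. With transcripts in place of gene sums, 96 rose and 73 fell in all 4 accessions, 1587 rose and 907 fell in MIDAS, and 2055 rose and 1702 fell in G12873. Without the 50 most abundant genes, 1764 rose and 1705 fell in MIDAS, and without MIDAS R8 replicate 2 it was 1534 and 1335. In G12873, 2160 rose and 1977 fell with a replicate block, 3233 and 3145 without a minimum fold change, and 3832 and 2311 without R7 replicate 3. In ICA Bunsi, 2318 rose and 2525 fell with RLE size factors, 2351 and 2701 with limma-voom, and 2326 and 2431 with DESeq2.

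The files pair no names with the gene identifiers, so genes are given by identifier. Phvul.009G126400 rose in every accession, from 12.5 ± 5.65 to 178 ± 52.3 CPM in MIDAS (SD, n = 3) and from 12.5 ± 6.29 to 536 ± 62.3 CPM in SXB405. Its log2 fold change was between 3.27 (SE 0.60, G12873) and 5.41 (SE 0.57, SXB405). The value in G12873 was 4.30 with limma-voom and 5.01 without the 8 libraries, with R7 replicate 3 alone at R7. The R7 libraries had 49.8, 15.2 and 4.69 CPM, the first 2 on 15 counts each. Phvul.L005301 rose from 1.13 ± 0.119 to 50.1 ± 23.6 CPM in SXB405 and from 2.02 ± 0.844 to 15.1 ± 4.16 CPM in MIDAS. Its log2 fold change was 2.29 in G12873, 5.54 in ICA Bunsi, 5.45 in SXB405 and 2.91 in MIDAS, a difference between accessions past the test (adjusted p = 0.00169). Phvul.011G065300 fell from 566 ± 90.0 to 40.1 ± 14.4 CPM in MIDAS and from 252 ± 30.6 to 20 ± 19.1 CPM in ICA Bunsi. Phvul.007G159100 fell from 32.9 ± 9.95 to 1.36 ± 0.899 CPM in SXB405, and in MIDAS from 29.7 ± 5.06 to 9.19 ± 2.06 CPM. Its step also differed between accessions (adjusted p = 0.0157).

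Some of these calls were lost when a library was left out. Without G12873 R7 replicate 3, the only library of that group in which the co-varying set took under 50%, the log2 fold change in G12873 went from 2.29 to 1.60 for Phvul.L005301 (adjusted p = 0.0503) and from -3.52 to -1.63 for Phvul.011G065300 (adjusted p = 0.501). For Phvul.011G065300 in G12873 the log2 fold change was -3.44 and -3.27 without R8 replicate 2 or 3 (adjusted p = 0.0668 and 0.0679) and -3.28 with a replicate block (adjusted p = 0.121). In ICA Bunsi it went from -3.65 to -3.33 and -3.25 without R8 replicate 1 or 3 (adjusted p = 0.0575 and 0.0604) and to -4.80 without R8 replicate 2 (adjusted p = 0.00749), and in MIDAS from -3.82 to -3.56 without R8 replicate 1 (adjusted p = 0.0624). For Phvul.007G159100 in MIDAS it went from -1.67 to -1.56 and -1.64 without R7 replicate 2 or 3 (adjusted p = 0.0591 and 0.0694), and to -1.62 and -1.51 without R8 replicate 1 or 2 (adjusted p = 0.0854 and 0.0911). With a replicate block it was -1.71 (adjusted p = 0.0541). On only the 6 samples compared, the rise of Phvul.L005301 in G12873 was 1.96 on the log2 scale (adjusted p = 0.0614).

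**Figure D2:**
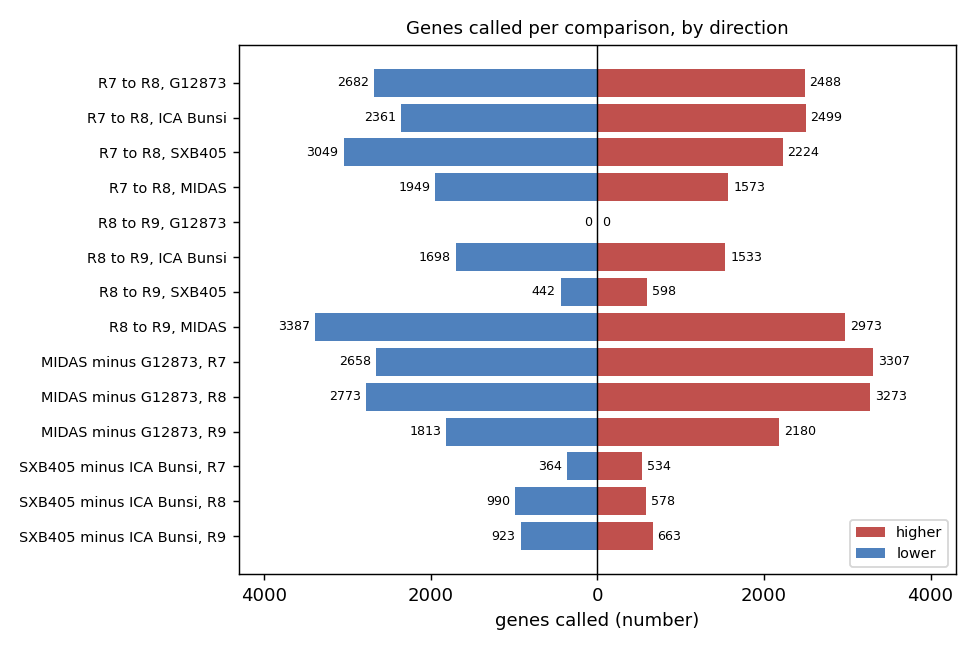
Number of genes called in each comparison (edgeR, adjusted p under 0.05 and at least a 2-fold change); red bars to the right are genes higher in the later stage or the first-named accession, blue bars to the left genes lower there. From R8 to R9 no gene was called in G12873, while 2973 rose and 3387 fell in MIDAS.

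From R8 to R9, as the pods matured, the counts of the accessions ranged from no called gene to 6360. In MIDAS, 2973 genes rose and 3387 fell. In ICA Bunsi 1533 rose and 1698 fell, and in SXB405 598 rose and 442 fell. No gene was called in G12873 by edgeR, where 1209 of the 20966 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.371. DESeq2 called 7 genes there and limma-voom 0. No gene was therefore shared by all 4 accessions, and 126 rose and 238 fell in all 3 domesticated ones. ICA Bunsi and MIDAS shared 913 rising genes (217.4 for independent lists) and 1035 falling ones (274.3 for independent lists).

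In G12873, 62 genes were called without R8 replicate 1 and 61 without R9 replicate 3, which gave 3 and 2 genes shared by all 4 accessions. The count in SXB405 was 435 without R8 replicate 1, 488 without R8 replicate 2 and 347 without R9 replicate 1, and it was 1916 in ICA Bunsi without R8 replicate 2 and 2124 without R9 replicate 3. Without the 8 libraries with over 50% of counts in the co-varying set, ICA Bunsi had 992 called genes, 875 of them among the original calls, with R9 replicate 2 as the lone R9 library and the spread taken from the other groups. SXB405 then had 631 (280 higher and 351 lower at R9), 489 of them among the original calls.

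The larger direction turned at this step as well. In ICA Bunsi 1746 rose and 1582 fell with RLE size factors, 1800 and 1593 with DESeq2, 1293 and 1067 on only the 6 samples compared, and 1005 and 911 without R8 replicate 2. In SXB405 124 rose and 136 fell with transcripts in place of gene sums and 184 and 214 on only the 6 samples. Leaving out SXB405 R8 replicate 1 or 2 gave 210 and 225 or 181 and 307, and leaving out R9 replicate 1 gave 167 and 180. Without R8 replicate 3, 377 of 722 genes fell. In MIDAS 3170 rose and 3094 fell with DESeq2.

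In MIDAS, Phvul.009G170800 rose from 6.67 ± 3.71 to 2248 ± 282 CPM (log2 fold change 8.39, SE 1.27, adjusted p = 1.01e-05). In G12873 and SXB405 the level of this gene at R8 was already 246 ± 81.1 and 1020 ± 344.6 CPM, and its step from R8 to R9 differed between the accessions (adjusted p = 0.000981). Phvul.008G250300 rose in MIDAS from 1.15 ± 0.50 to 360 ± 518 CPM, with 958, 47.9 and 73.9 CPM in R9 replicates 1, 2 and 3. Replicate 1 is one of the 8 libraries over 50%, and without it the log2 fold change went from 8.21 to 5.64 (adjusted p = 3.19e-07). Phvul.004G068300 fell in MIDAS from 23.1 ± 2.94 to 1.17 ± 2.03 CPM and Phvul.005G046700 from 29.1 ± 5.40 to 1.07 ± 1.30 CPM. No count of Phvul.004G068300 was found in MIDAS R9 replicates 2 and 3, whose depth allowed up to 0.345 and 0.416 CPM (3 counts, counting error only), so its fold change there is not a measured size. At R8 these 2 genes stood at 4.48 ± 3.17 and 0.711 ± 0.331 CPM in SXB405. The steps of all 3 differed between accessions, with adjusted p = 0.000348, 0.0375 and 0.00123 in that order.

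In ICA Bunsi, Phvul.011G209600 fell from 1237 ± 1185 to 12.1 ± 5.55 CPM, a log2 fold change of -6.76 that was -5.65 without R8 replicate 2. It also fell in SXB405 (261 ± 251 to 9.38 ± 6.01 CPM) and in MIDAS (1483 ± 186 to 80 ± 100.5 CPM). In G12873 it stood at 651 ± 119 CPM at R7 and at 4.85 ± 2.21 CPM already at R8. Phvul.003G218700 fell in SXB405 from 634 ± 110 to 9.98 ± 5.29 CPM, with a log2 fold change of -5.99 against -2.35 in ICA Bunsi and -3.71 in MIDAS. The steps of both genes differed between accessions (adjusted p = 0.0213 and 0.0316). Phvul.008G213800 rose in SXB405 from 2.45 ± 0.701 to 78.3 ± 53.5 CPM and was at or under 2.17 CPM in the group means of the other accessions (adjusted p of the difference = 0.00027). Phvul.011G091300 fell in ICA Bunsi, by 4.70 on the log2 scale.

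Calls of other named genes were lost in some fits too. Phvul.011G205400 rose in ICA Bunsi from 1.55 ± 1.74 to 131 ± 62.8 CPM, a log2 fold change of 6.38 (adjusted p = 0.0221). It was 7.69 with limma-voom (adjusted p = 0.133) and 6.20, 7.76 and 5.79 without R8 replicate 1, 2 or 3 (adjusted p = 0.0760, 0.0566 and 0.0733). Without R9 replicate 1 it was 5.89 (adjusted p = 0.0565). Phvul.L002290 rose in ICA Bunsi from 9.94 ± 6.27 to 711 ± 654 CPM. R9 replicates 1, 2 and 3 had 789, 20.5 and 1323 CPM, and the co-varying set took over 50% in replicates 1 and 3. The gene was also higher in the libraries over 50% of G12873 R7 (1713 and 186 against 12 CPM), ICA Bunsi R7, MIDAS R8 and MIDAS R9. In SXB405 R9 that library had 70.2 CPM, under the 87.9 CPM of replicate 2. In ICA Bunsi the log2 fold change of Phvul.L002290, 6.16, was 5.87 and 5.95 without R8 replicate 2 or 3 (adjusted p = 0.0890 and 0.0654). It was 5.27 without R9 replicate 3 (adjusted p = 0.060) and 4.86 with a replicate block (adjusted p = 0.0844). Without the 8 libraries named above, with R9 replicate 2 alone at R9, it was 1.06 (adjusted p = 0.40) and that of Phvul.011G205400 5.43 (adjusted p = 0.113).

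Phvul.005G181800 rose in SXB405 from 2.03 ± 0.893 to 46.1 ± 67.1 CPM. Its log2 fold change of 4.46 was 1.83 without SXB405 R9 replicate 1 (adjusted p = 0.325), and 4.20 and 4.45 without R8 replicate 1 or 2 (adjusted p = 0.0761 and 0.0693). It was 2.93 with limma-voom (adjusted p = 0.183), 3.42 with a replicate block (adjusted p = 0.104) and 1.82 without the 8 libraries (adjusted p = 0.296). For Phvul.011G091300 in ICA Bunsi the log2 fold change of -4.70 was -1.97 without R8 replicate 2 (adjusted p = 0.185) and -3.56 without R9 replicate 2 (adjusted p = 0.0534). On only the 6 samples compared, the log2 fold change of Phvul.011G209600 in SXB405 was -4.81 with an adjusted p of 0.126, against -4.81 and 0.00519 over all samples. There Phvul.011G091300 had -4.70 in ICA Bunsi (adjusted p = 0.109) and Phvul.005G181800 had 4.53 in SXB405 (adjusted p = 0.172).

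MIDAS was then compared with G12873 at each stage, the indehiscent against the fully dehiscent accession. With 1 accession of each kind, this difference is one between accessions. At R7, 3307 genes were higher and 2658 lower in MIDAS. At R8 the numbers were 3273 and 2773, and at R9 2180 and 1813. On component 1 the R8 libraries of MIDAS lay next to its R7 libraries and those of G12873 next to its R9 libraries. A difference at R8 therefore cannot be told apart from one of stage. At all 3 stages, 411 genes were higher and 432 lower. At R7 the larger direction turned, with 2869 higher and 2988 lower without the 50 most abundant genes, 1977 and 2139 without the 8 libraries over 50%, which leaves replicate 3 alone in G12873 R7, and 2292 and 2307 without G12873 R7 replicate 2. On only the 6 samples compared, 1607 were higher and 1494 lower at R7, and 1236 and 798 at R9.

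Phvul.002G022200 had 1.77 ± 0.683, 7.21 ± 1.24 and 3.83 ± 2.67 CPM in MIDAS at R7, R8 and R9 (SD, n = 3), against 104 ± 27.8, 319 ± 61.1 and 392 ± 56.7 CPM in G12873. Phvul.004G158000 reached 13580 ± 3468 CPM in G12873 and 15500 ± 4862 CPM in SXB405 at R9, and it had 77.3 ± 39.0 CPM in MIDAS and 17.0 ± 8.51 CPM in ICA Bunsi.

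In the other direction, Phvul.010G135000 had 185 ± 16, 700.4 ± 213 and 295 ± 184 CPM in MIDAS against 34.3 ± 35.1, 11.2 ± 4.49 and 13.6 ± 12 CPM in G12873. Phvul.011G204700 stood at 1693 ± 331 CPM in MIDAS and 2.23 ± 1.07 CPM in G12873 at R8, a log2 difference of 9.59 (SE 1.61, adjusted p = 4.82e-05). Its means at R7 and R9 were 3874 ± 811 and 209 ± 324 CPM in MIDAS, and 269 ± 190 and 1.28 ± 0.456 CPM in G12873. As its level went down with stage in both, its difference at R8 can also be one of stage. At R7 its log2 difference of 3.82 (adjusted p = 0.0181) was 3.32 without G12873 R7 replicate 1 (adjusted p = 0.0684), and 3.32 without the 8 libraries (adjusted p = 0.0945). At R9 its log2 difference of 7.35 was 4.53 with limma-voom (adjusted p = 0.121) and 4.13 without MIDAS R9 replicate 1 (adjusted p = 0.0159). For Phvul.010G135000 at R7 the log2 difference of 2.91 was 2.07 without G12873 R7 replicate 3 (adjusted p = 0.0712) and 3.95 without its replicate 1. It was 4.49 with limma-voom and 5.28 without the 8 libraries, with R7 replicate 3 alone in G12873. At R9 it went from 4.46 to 5.47 without G12873 R9 replicate 1.

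SXB405 and ICA Bunsi carry the same dehiscence label. SXB405 had 534 genes higher and 364 lower than ICA Bunsi at R7, 578 and 990 at R8, and 663 and 923 at R9. At all 3 stages, 98 genes were higher and 76 lower in SXB405. Phvul.010G144300 had the largest mean difference among the genes eligible for naming, with 22370 ± 11300 CPM in SXB405 and 111 ± 83 CPM in ICA Bunsi at R8. It was also abundant in G12873 at R9 (21510 ± 6191 CPM) and had 2271 ± 2098 CPM in MIDAS. Phvul.001G137800 had 61.9 ± 6.49, 43.3 ± 15.2 and 49.4 ± 11.2 CPM in SXB405 over the 3 stages and 13.1 ± 2.25, 2.73 ± 0.810 and 5.06 ± 0.628 CPM in ICA Bunsi. Phvul.002G317500 was lower in SXB405, with 1.01 ± 0.333 to 2.51 ± 0.343 CPM, than in ICA Bunsi, with 22.8 ± 5.44 to 30.6 ± 4.99 CPM. Phvul.011G014301 was lower as well, by log2 differences of -3.09, -3.78 and -4.58 at R7, R8 and R9.

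These counts depended on the fit and on single libraries. On only the 6 samples compared they were 1722 at R7, 501 at R8 and 746 at R9. At R7 DESeq2 gave 512 genes higher and 583 lower. The count of 898 at R7 became 407 and 422 without ICA Bunsi R7 replicate 2 or 3, and 519, 585 and 520 without SXB405 R7 replicate 1, 2 or 3. The count of 1568 at R8 was 756 without ICA Bunsi R8 replicate 2, 2643 without SXB405 R8 replicate 1, and 564 and 720 without its replicate 2 or 3. The count of 1586 at R9 was 704, 2686 (1356 higher and 1330 lower) and 952 without ICA Bunsi R9 replicate 1, 2 or 3, and 918 without SXB405 R9 replicate 3. Without the 8 libraries with over 50% of counts in the co-varying set it was 293, with 1 library of ICA Bunsi at R9 (replicate 2), assumed to vary like the other groups.

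Genes known from earlier work on pod dehiscence were fixed as candidates before the data were examined. They are Phvul.002G271000 (PvIND), related to INDEHISCENT, which patterns the valve margin in Arabidopsis fruits, Phvul.003G252100 (PvPdh1), related to the dirigent-like Pdh1 of soybean pod shattering, and Phvul.005G157600 (PvMYB26), related to MYB26, a regulator of secondary wall thickening in anthers. The names come from the literature, not from the files. MIDAS was set against the mean of the other 3 accessions at each stage.

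The dirigent gene Phvul.003G252100 was higher in MIDAS at each stage. It had 43.3 ± 7.45, 82.6 ± 6.87 and 146 ± 38.2 CPM in MIDAS at R7, R8 and R9 (SD, n = 3), and the highest group mean among the other accessions was 16.1 CPM. The log2 differences from the mean of the others were 2.67 (SE 0.26), 2.82 (SE 0.24) and 3.29 (SE 0.25), with adjusted p = 4.49e-09, 2.29e-10 and 1.43e-11. At each stage all 3 MIDAS libraries lay above all 9 others. The size of its steps was not found to differ between accessions (adjusted p = 0.306 and 0.529).

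The PvIND gene Phvul.002G271000 was expressed at a low level, with 2.77 ± 0.736 and 1.84 ± 0.662 CPM in MIDAS at R7 and R8, and rose to 15.9 ± 2.07 CPM at R9. The log2 differences from the mean of the others were 1.76 (SE 0.45, adjusted p = 0.00233), 2.06 (SE 0.45, adjusted p = 0.000501) and 4.33 (SE 0.41, adjusted p = 1.78e-09). At R8 and R9 all 3 MIDAS libraries lay above all 9 others. Its rise from R8 to R9 was 3.11 on the log2 scale in MIDAS and 2.56 in ICA Bunsi, both past the test, and 0.92 in SXB405 and -0.97 in G12873, which did not pass it. The values in ICA Bunsi at R9 were 4.72, 0.478 and 2.81 CPM on 10, 6 and 3 counts. The high ones are replicates 1 and 3, in which the co-varying set took over 50% of the counts, and replicate 2 lay within the range at R8, 0.163 to 0.587 CPM. This step differed between accessions (adjusted p = 0.00496), a test over all libraries. No count of the gene was found in G12873 R7 replicates 1 and 2, whose depth allowed up to 9.96 and 3.03 CPM (3 counts, counting error only), so at R7 these libraries cannot be placed below MIDAS.

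The PvMYB26 gene Phvul.005G157600 fell at different steps. In G12873 it stood at 58.6 ± 8.48 CPM at R7 and fell by 6.74 on the log2 scale to 0.536 ± 0.107 CPM at R8. In MIDAS it had 11.5 ± 1.58 CPM at R7 and 22.3 ± 3.18 CPM at R8, and fell to 2.58 ± 1.26 CPM at R9. In ICA Bunsi and SXB405 it had 1.37 ± 0.198 and 1.66 ± 0.623 CPM at R7. Both steps differed between accessions (adjusted p = 3.21e-08 and 0.0253). Against the mean of the others, MIDAS was higher by 1.16, 4.79 and 2.88 on the log2 scale (SE 0.32, 0.32 and 0.51) with adjusted p = 0.00479, 1.17e-12 and 6.68e-05. At R7 this mean hides 2 directions, since MIDAS was lower than G12873 (log2 difference -2.37, adjusted p = 6.54e-05) and 0 of its 3 libraries lay above all 9 others. At R9 the MIDAS libraries had 4.02, 2.07 and 1.67 CPM on 8, 18 and 12 counts, and the other libraries had 0 to 5 counts. ICA Bunsi R9 replicate 3 had 0 counts at a depth that allowed up to 2.81 CPM (3 counts, counting error only). It cannot be placed below MIDAS replicates 2 and 3. Adjusted over the candidates alone, the 9 tests of the 3 genes gave adjusted p of at most 0.00102.

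**Figure D3:**
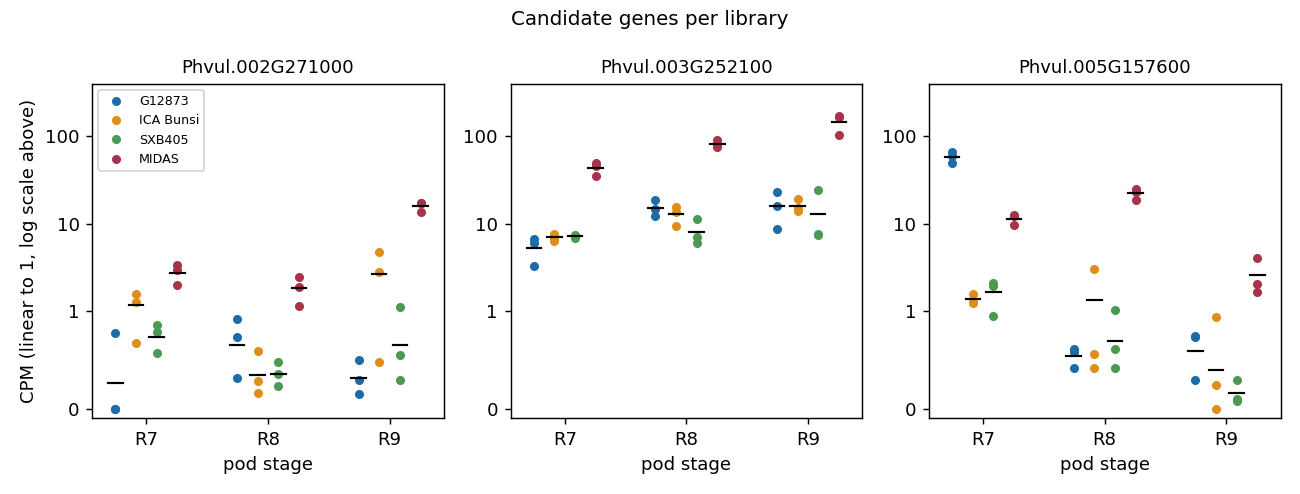
CPM of the candidate genes in each library (points) with group means (lines), by stage and accession; the axis is linear up to 1 CPM and logarithmic above. The group means of MIDAS lie above the others in all panels and stages except Phvul.005G157600 at R7, where G12873 has 58.6 ± 8.48 CPM (SD, n = 3). For Phvul.002G271000, G12873 R7 replicates 1 and 2 have 0 counts and depth for up to 9.96 and 3.03 CPM, so they cannot be placed below MIDAS. For Phvul.005G157600, ICA Bunsi R9 replicate 3 has 0 counts and depth for up to 2.81 CPM, so it cannot be placed below MIDAS R9 replicates 2 and 3.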

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

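The steps below were looked at again because the change of a named gene differed between the 4 accessions, by an F-test of the difference itself with adjustment over all genes tested. The candidates were taken at both steps and other genes only at the step for which they were named. The rule and the tests were planned, but the rule picked the other genes from these data, and from R8 to R9 by their change in a single accession, which favours a difference between accessions.

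From R7 to R8 Phvul.005G157600 (PvMYB26) fell by 6.74 on the log2 scale in G12873 and had a log2 fold change of 0.95 in MIDAS (adjusted p = 3.21e-08). Phvul.L005301 rose in all accessions, with log2 fold changes from 2.29 in G12873 to 5.54 in ICA Bunsi (adjusted p = 0.00169). Phvul.007G159100 fell in all, by 1.67 in MIDAS and by 4.62 in SXB405 (adjusted p = 0.0157).

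From R8 to R9 Phvul.002G271000 (PvIND) had log2 fold changes of 3.11 in MIDAS and, on 10, 6 and 3 counts at R9, 2.56 in ICA Bunsi, with an adjusted p of 0.00496 for the difference between accessions. Phvul.005G157600 fell by 3.28 in MIDAS and had a log2 fold change of 0.05 in G12873 (adjusted p = 0.0253). The value in G12873 rests on 3 to 10 counts per library. Phvul.009G170800 had log2 fold changes of 8.39 in MIDAS, 3.10 in ICA Bunsi and 0.00 in SXB405 (adjusted p = 0.000981). Phvul.008G250300 had 8.21 in MIDAS, or 5.64 without R9 replicate 1, and -0.07 in G12873 (adjusted p = 0.000348 over all libraries). Phvul.005G046700 had -5.51 in MIDAS and 0.46 in SXB405 (adjusted p = 0.00123), and Phvul.004G068300 had -5.65 in MIDAS, with 0 counts in R9 replicates 2 and 3, and -0.40 in G12873 (adjusted p = 0.0375). Phvul.008G213800 had 4.98 in SXB405 and -0.86 in MIDAS (adjusted p = 0.00027). Phvul.011G209600 had -6.76 in ICA Bunsi, or -5.65 without R8 replicate 2, and -0.98 in G12873 (adjusted p = 0.0213), and Phvul.003G218700 had -5.99 in SXB405 and -2.35 in ICA Bunsi (adjusted p = 0.0316).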

How the results depend on the processing

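All counts below are of called genes; the fit without 8 libraries was chosen after seeing the data and the rest were planned. Of the 16 counts, all stayed within 1.5 times under RLE size factors, limma-voom, no filter, no minimum fold change, effective lengths and without the 50 most abundant genes. The cause of the changes below was not tested. Tests on gene lists were not run, as no list could be formed. No named gene reversed its direction. Of 52 named values, limma-voom lost 3 calls, the 6-sample fit 4, the fit without 8 libraries 4 and the replicate block 4; leaving out single libraries lost 25 of 312. The 9 candidate values kept their calls in every alternative in which they were fitted. The 6-sample fit did not hold the contrast of the candidates. With transcripts in place of genes, and without a minimum fold change, only counts were taken and no named value.

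With transcripts in place of genes, R8 to R9 gave 2137 in ICA Bunsi and 260 in SXB405, SXB405 minus ICA Bunsi gave 445 (R7), 550 (R8) and 789 (R9), and 169 were shared from R7 to R8. With DESeq2, G12873 had 7 from R8 to R9. On only the 6 samples compared, R7 to R8 gave 1922 in G12873 and R8 to R9 gave 398 in SXB405. MIDAS minus G12873 gave 3101 (R7) and 2034 (R9), and 210 were shared from R7 to R8. SXB405 minus ICA Bunsi gave 501 (R8) and 746 (R9) but rose from 898 to 1722 at R7. The main fit shared 1 spread over groups whose replicates agreed unequally. Pearson's r was 0.707 to 0.773 in G12873 R7 and 0.983 to 0.988 in SXB405 R7. Whether sharing it calls too many genes in groups of wide spread was not tested. Without the 8 libraries, which leaves 1 each in G12873 R7 and ICA Bunsi R9 and takes the spread from all groups, R8 to R9 gave 992 in ICA Bunsi and 631 in SXB405, and SXB405 minus ICA Bunsi 293 at R9.

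The replicate block gave 538 for R8 to R9 in SXB405 and moved no other count by over 1.5 times. Of same-number pairs, 2 of 24 in steps and 1 of 18 in accession differences correlated over 0.1. The highest of these in steps, 0.259, was in that SXB405 step. Pairs of unlike number reached 0.287 in steps and 0.332 in accession differences. No pairing was found, but these correlations cannot exclude it.

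Leaving out each library in turn gave, from R7 to R8, 4001 to 6143 in G12873, 3713 to 5166 in ICA Bunsi, 4601 to 5238 in SXB405, 2027 to 3570 in MIDAS and 263 to 499 shared. From R8 to R9 it gave 0 to 62 in G12873, 1916 to 3942 in ICA Bunsi, 347 to 1122 in SXB405, 5450 to 6241 in MIDAS and 0 to 3 shared. MIDAS minus G12873 gave 4599 to 7184 (R7), 5173 to 6014 (R8) and 3326 to 3871 (R9). SXB405 minus ICA Bunsi gave 407 to 897 (R7), 564 to 2643 (R8) and 704 to 2686 (R9). The libraries behind these are named with the counts in the results.

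The median log2 fold change of all genes moved by over 0.1 in G12873 from R7 to R8 under DESeq2 (-0.11) and without the 8 libraries (-0.13), and in MIDAS minus G12873 at R7 without the 8 libraries (-0.18). Depth limited G12873 R7 most, where 3 counts stood for 9.96 CPM in replicate 1.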

Other observations

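Most tests here were chosen after the results were seen; written before were the test of the G12873 step on the genes of the domesticated accessions and the direction of neighbouring genes.

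A few genes were near absent in 1 accession, chosen after their values were seen as those with under 1 read in all 9 libraries of an accession and a mean of at least 5 CPM in each other accession. Phvul.002G209500 and Phvul.L001601 had 0 reads in ICA Bunsi and were at least 204-fold and 171-fold higher in every other accession, against a floor of 3 reads over the 9 libraries. Phvul.007G117500 and Phvul.010G135101 had 0 reads in MIDAS and were at least 149-fold and 312-fold higher elsewhere. The floors cover counting error only. By its identifier Phvul.010G135101 is numbered close to Phvul.010G135000, which was higher in MIDAS than in G12873 at all 3 stages. Whether reads were divided differently between similar genes, or sequence variants against the reference gave the 0 reads, was not tested.

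Across 20966 genes, which are not independent replicates, the fold changes of MIDAS from R8 to R9 correlated with those of G12873 from R7 to R8 (Pearson's r = 0.535) and of SXB405 from R7 to R8 (r = 0.531), more than with R8 to R9 in these accessions (r = 0.171 and 0.376). For ICA Bunsi it was the other way round, with r = 0.369 for R7 to R8 and 0.541 for R8 to R9. The changes of MIDAS from R7 to R8 correlated with the same step in ICA Bunsi at r = 0.390, in SXB405 at 0.356 and in G12873 at 0.10. With R8 to R9 of the others they correlated at r = 0.184 in G12873, above the value for its R7 to R8. In ICA Bunsi and SXB405 r was -0.029 and -0.025. These accessions share no libraries. The difference MIDAS minus G12873 correlated with the R9 minus R7 change of the 2 other accessions at r = -0.483 at R8, and at r = -0.080 and 0.080 at R7 and R9.

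Each library was placed between the R7 mean (0) and the R9 mean (1) of its accession, along the change seen in the other accessions. The R8 libraries stood at 0.834 ± 0.0505 in G12873, 0.771 ± 0.0609 in SXB405, 0.581 ± 0.209 in ICA Bunsi and 0.156 ± 0.0543 in MIDAS (SD, n = 3). The exact two-sided permutation p for MIDAS against each other accession was 0.1, the smallest that 3 against 3 libraries allow, and 0.15 after adjustment over 6 pairs. The SD and the p leave out the spread of the R7 and R9 libraries that set 0 and 1. In G12873 these ran from -0.202 to 0.193 and from 0.880 to 1.152.

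Reads of the co-varying genes do not account for the R8 libraries of MIDAS standing near R7. Without the libraries over 50%, MIDAS stood at 0.178 at R8, on replicates 1 and 3, in which the set took 2.99% and 2.96%. Nor does 1 wrong label among the R8 libraries of MIDAS, the highest of which stood at 0.194. For G12873 near R9 this removal cannot decide, as it takes out no R8 library and leaves R7 replicate 3 alone to set 0. Leaving only the co-varying genes out of the calculation kept G12873 at 0.8345 and MIDAS at 0.1561, which does not address low depth. For the genes that change in the domesticated accessions, a hidden step in G12873 as large as there is argued against. Over the 364 genes called from R8 to R9 in the 3 domesticated accessions, the median change of G12873 in their direction was 0.35 on the log2 scale. This is under 0.96, a bound set from the medians of those accessions, 1.93 to 3.27, which the choice of genes can raise. With genes called in 2 of these accessions, the G12873 median was at most 0.235 times that of the third, which had no part in the choice. A smaller step is not excluded, as 78% of the 364 genes went the same way in G12873. A step of G12873 in other genes is not addressed by these medians. A candidate explanation is that R8 pods were taken at different points of one course in the accessions; a slower course in MIDAS and an earlier sampling of it stay open and untested.

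The share of counts in the 10 co-varying genes varied 44.2-fold over libraries. Accession and stage are argued against as its whole cause: the groups held 44.3% of the variance of the log2 share (permutation p = 0.13), and replicates of G12873 at R7 ran from 7.32% to 86.5%, though a part is not excluded. A common source of reads, such as carry-over of abundant RNA or differing RNA quality, cannot be told apart from other causes. The ratio of the second to the first gene varied 2.03-fold, just over the bound of 2 set for it. The ratio to the first gene that varied most among the members did so 9.24-fold. Differences between the plants sampled stay open and untested.

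Genes that differed between SXB405 and ICA Bunsi at all 3 stages stood next to each other more often than chance, if identifiers number genes along a chromosome, a convention that was not checked. Genes whose identifier gives no chromosome were left out here and below, which keeps 172 of the 174 genes. Among these 172, 13 pairs were adjacent against 1.78 on average in 10000 permutations within chromosomes (p = 1e-04, the smallest they can give). By Fisher's exact test adjusted over 11 chromosomes, chromosomes 4 (28 of 1302 tested genes, p = 3.77e-05) and 11 (24 of 1565, p = 0.0124) held more of them and chromosomes 9 (4 of 2150, p = 0.000441) and 7 (8 of 2066, p = 0.0411) fewer. This test takes genes as independent, while these stood next to each other, so its p-values can be too small. Genes that differed between MIDAS and G12873 at all 3 stages made up 4.69% and 5.11% of the tested genes on chromosomes 4 and 11. On chromosomes 9 and 7 they made up 4% and 3.68%.

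An exchange of reads between near-identical neighbours, in which 1 gains what the other loses, is argued against, since 7.69% of the pairs (1 of 13) went in opposite directions. Reads shared by both neighbours would instead move them in the same direction, as 1 signal counted in both. The directions cannot tell this apart, so it stays open and untested. Neighbours that respond together in any comparison stay open. The ratio of pairs to chance was 7.31 here, 1.46 for 489 of the 499 genes changed from R7 to R8 in all accessions (permutation p = 0.078) and 2.05 for 831 of the 843 that differed between MIDAS and G12873 at all stages (permutation p = 1e-04), but these lists differ in length. For the 172 genes with the largest changes of each list it was 4.20 (permutation p = 0.003) and 7.10 (permutation p = 1e-04). Blocks of the genome in which the accessions differ may also give this, and sequence variants against the reference, or arrays that differ in copy number, stay open and untested.

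Other splits of the same libraries were fitted on the 6 libraries of a comparison. With 10 splits of 3 against 3 no share under 0.05 is possible. The real split was the only 1 of 10 to reach its count from R7 to R8, with 1922 genes in G12873, 4450 in ICA Bunsi, 5331 in SXB405 and 3865 in MIDAS, and from R8 to R9 with 2360 in ICA Bunsi, 398 in SXB405 and 5013 in MIDAS; the highest other split gave 0. In G12873 from R8 to R9 all 10 splits gave 0. MIDAS minus G12873 gave 3101, 5512 and 2034 genes at R7, R8 and R9 with 0 in the highest other split, and SXB405 minus ICA Bunsi gave 1722 and 501 at R7 and R8 with 0, and 746 at R9 with 5. For the genes shared by all 4 accessions from R7 to R8, the real count of 210 was reached by 1 of 100 splits, the real one, and the highest other was 0. This follows from the 0 genes in the other splits of each accession and adds nothing to them, so it is not taken to exclude chance. From R8 to R9 the real count was 0, which all 100 of 100 splits reach by construction, so the splits say nothing there.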
